A study of Mus musculus with 4 samples.

How the data were processed

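The study profiled single cells from C57BL/6J mouse embryos to follow the ontogeny of lymphoid tissue inducer (LTi) cells, the fetal innate lymphocytes that start lymph node formation. Live CD45+ F4/80- IL7Ra+ cells were sorted after magnetic enrichment of CD45+ cells, per the labels' protocols. There were 4 libraries, 1 per stage (E13.5 and E14.5) for each of fetal liver and embryonic periphery. Periphery was prepared with version 2 and fetal liver with version 3 of the 10x Genomics Chromium 3' kit, and all were sequenced on NextSeq 500/550 High Output v2 cartridges of 75 cycles. Kit and tissue therefore coincide, and no difference between the tissues can be separated from the kit.

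The deposited matrices hold UMI counts per gene and barcode, with no normalization, as checked on the files. Per the submitters' processing notes they were made with Cell Ranger version 3 on mm10, and per the file headers with version 3.0.0 for fetal liver and 3.0.1 for periphery. The feature lists differ, with 31053 genes for fetal liver and 28427 for periphery, of which 27566 were shared by Ensembl ID and 1302 of these carried another symbol. The gene model releases behind the lists are not given in the sources used here. Coordinates on GRCm38/mm10 came from GENCODE M21, which held 31251 of the 31914 joined features and all 245 named genes.

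A barcode was kept with at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy, with an expected rate of 0.8% per 1000 barcodes. Its automatic threshold was used where it marked 0.5 to 15% of barcodes, which held for fetal liver at E14.5 only. In the other 3 libraries the top-scored barcodes were marked up to the expected rate, with barcodes tied at the limit not marked. This gave 8.05% in fetal liver at E13.5 and 3.13 and 3.71% in periphery, and all marked doublets were left out. This left 9773 cells of E13.5 and 10892 of E14.5 fetal liver, and 4166 cells of E13.5 and 4325 of E14.5 periphery. Barcodes below the gene minimum numbered 58, 90, 97 and 312 in that order, barcodes above the mitochondrial limit 119, 341, 177 and 322, and marked doublets 868, 815, 142 and 186.

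Cells of each tissue were clustered over its 2 stages. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen without haemoglobin, mitochondrial, ribosomal and cell-cycle genes. Then followed 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1. Clusters were named from 19 fixed marker sets and are called like cells, since no independent label exists. A marker counted as detected at 20 CPM or more and at least 1 log2 unit above the lower quartile of clusters. A class was eligible with at least 3 and over 50% of its markers detected and a mean marker level above the mean of the clusters. The eligible class with the highest level gave the name, unless the 10 leading genes of the cluster held more markers of another class. In that case the next eligible class was tried, and a cluster without a name stayed unnamed. The marker sets were fixed beforehand, but this naming rule was settled after several versions had been tried on the data. Clusters FL10, P2 and P5, in which more than 1 innate lymphoid class was eligible and the eligible class with the highest level was innate lymphoid but not LTi, were also split into sub-clusters with the same settings, a step added after the data had been seen.

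Expression was computed here as CPM, each gene's share of all UMIs on the usual scale, from UMIs summed over all kept cells, or over the cells of a class with at least 50 cells in each library. A gene was measured at 10 CPM or more in either library. The log2 fold was taken after adding 5 CPM to both sides, which understates folds of weakly detected genes. Except where stated, each fold and each list median is given minus the median fold of all measured genes of the same comparison. That median was -0.03 between stages in fetal liver, 0.23 in periphery, -0.41 between tissues at E13.5 and -0.17 at E14.5. Within LTi-like cells of periphery it was 0.23. Within LTi-like sub-clusters it was 0.03 between stages in fetal liver, and -0.39 and -0.15 between tissues at E13.5 and E14.5. Exact Poisson intervals at 95% stand in parentheses after CPM values, and exact Clopper-Pearson intervals after shares of cells. Both cover counting error only. With 1 library per group no significance test was made and no p-value is given, and cells were not used as replicates. Where technical explanations were weighed, sets of genes were chosen by their fold before the all-gene median was taken off. Folds of these sets are given on that scale, and the sizes of the sets are no counts of significant changes.

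For 25 fixed gene lists the median log2 fold was placed among those of 10000 random lists of the same size, matched on expression in 20 bins. The percentile describes these libraries and is no test, and lists with fewer than 5 measured members gave no reported median. For 22 genes the share of cells with a UMI was taken after thinning each cell to 3000 UMIs and leaving out shallower cells. Cxcr6 was put first among them after the data had been seen, and results of a few genes are not reported here. Fractions of cells in B lineage-like cells served as background, except for genes such as Il7r that B lineage cells express.

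The genes to name followed a fixed rule. It took the 8 highest and 8 lowest folds of each stage comparison, over all kept cells at 20 CPM and 50 UMIs or more in the higher library, and within LTi-like cells at 20 CPM and 30 UMIs or more. Where no LTi-like class had 50 cells in both libraries, the innate lymphoid progenitor-like class took its place. Between tissues the same numbers were taken among genes at least 2-fold different in the same direction at both stages, ranked by the smaller fold. Mitochondrial, ribosomal protein and haemoglobin genes, Xist, Tsix, Y-linked genes and unnamed gene models were left out, while other X-linked genes were kept. Added to these were the 2 highest and 2 lowest members of each list described and the 22 genes above. The groups, comparisons, gene lists, marker sets, naming of genes and 22 alternatives were fixed before the data were examined.

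The fold and list steps were tested on simulated Poisson counts drawn from the pooled profile of the 2 stages of each tissue. With 200 genes set to known folds, all had the right direction, and the 95% intervals held the true fold for 92 to 100% of them and for 94.7 to 94.9% of unaltered genes. Of 200 unaltered lists, 7.0% in periphery and 5.5% in fetal liver lay beyond the 2.5th or 97.5th percentile, so a percentile near these bounds is weak evidence. In periphery at E13.5 the largest gap between a thinned share and its exact expectation over 200 genes was 1.90 percentage points. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.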

Results

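Sorted CD45+ F4/80- IL7Ra+ cells of mouse fetal liver and embryonic periphery were profiled at E13.5 and E14.5, with 1 library per group. The deposited matrices hold 212034840 and 208229937 UMIs for fetal liver at E13.5 and E14.5, and 53229734 and 44599592 for periphery. Kept cells had median depths of 18193, 15650, 11121 and 8457 UMIs in the same order. No replicate check of any value is possible, so every comparison describes these 4 libraries. Haemoglobin took at most 0.0354% of UMIs in any library, and ribosomal protein genes took 19.1 and 19.4% in fetal liver against 29.4 and 23.9% in periphery.

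The first comparison asked how the IL7Ra+ cells of fetal liver differed between E13.5 and E14.5. B lineage-like cells made up 7.77% (7.24 to 8.31) of kept cells at E13.5 and 40.7% (39.7 to 41.6) at E14.5, mostly in clusters FL12 and FL13 at the earlier stage and FL15, FL17 and FL12 at the later. Mast cell or basophil-like cells of cluster FL16 were 1.16% (0.954 to 1.39) and 6.60% (6.14 to 7.08). Stem and multipotent progenitor-like cells, mostly of cluster FL11, were lower at E14.5, with 11.2% (10.6 to 11.8) against 3.02% (2.71 to 3.36). Lymphoid progenitor-like cells of clusters FL0, FL1, FL6 and FL7 stood at 33.8% (32.9 to 34.8) and 30.4% (29.6 to 31.3). These totals join opposite changes. FL0 was lower at E14.5 (15.8 and 4.79%), while FL1 (4.17 and 7.88%), FL6 (7.07 and 9.21%) and FL7 (6.74 and 8.56%) were higher. Innate lymphoid progenitor-like cells of clusters FL8 and FL10 stood at 7.91% (7.38 to 8.46) and 6.18% (5.73 to 6.65), and neutrophil lineage-like cells of cluster FL14 at 2.18% (1.90 to 2.49) and 1.19% (0.998 to 1.42). No main cluster of fetal liver was named LTi-like, while sub-clusters of FL10, defined later, held LTi-like cells at 3.14 and 1.88%, and other seeds gave LTi-like clusters of up to 3.55 and 2.18%. Clusters FL3 and FL4, with 1 and 2 stem cell markers among their 10 leading genes, stayed unnamed with 20.3 and 4.96% of the cells, as did FL5 and FL9 with 15.6 and 6.65%. All shares refer to the sorted gate and to the version 3 kit, and several depend strongly on the clustering. Over the alternative clusterings and cell filters, B lineage-like cells ranged from 4.001 to 14.48% at E13.5 and from 36.4 to 49.7% at E14.5. Stem and multipotent progenitor-like cells ranged from 0 to 22.2% and from 0 to 4.001%, lymphoid progenitor-like cells from 9.14 to 53.1% and from 15.6 to 43.2%, and innate lymphoid progenitor-like cells from 3.72 to 23.8% and from 1.74 to 10.5%.

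**Figure D1:**
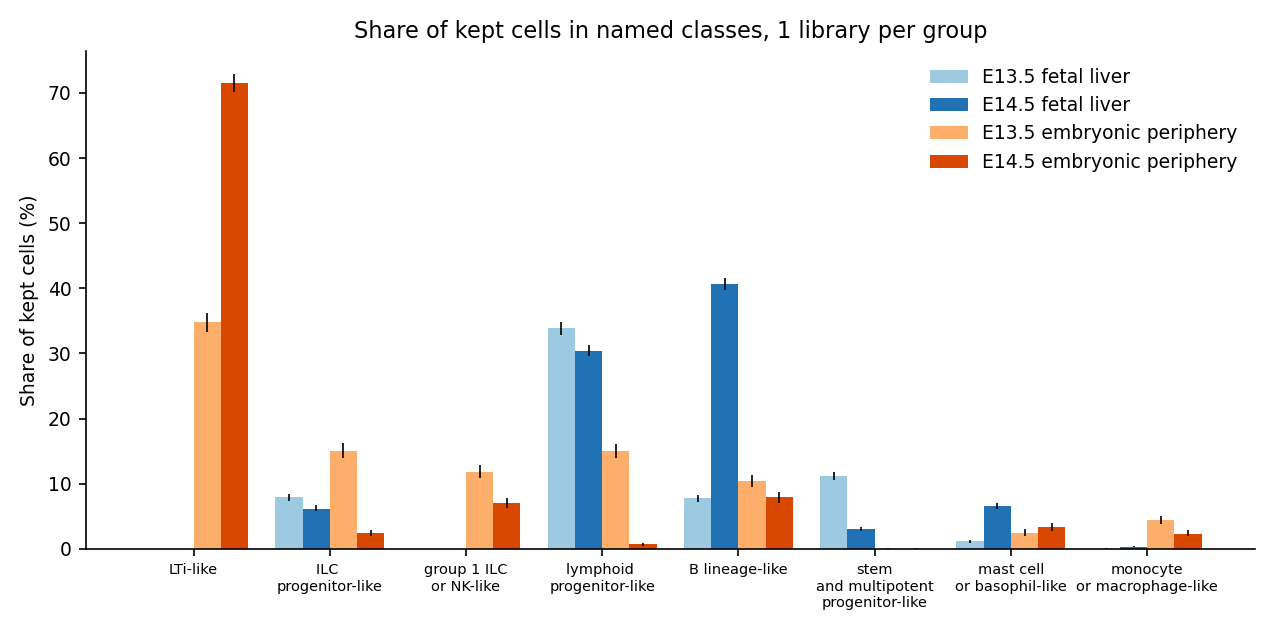
Share of kept cells (percent, vertical axis) in each named class for the 4 libraries, with exact 95% intervals that cover counting error only. B lineage-like cells of fetal liver stood at 7.77% at E13.5 and 40.7% at E14.5 and LTi-like cells of periphery at 34.8% and 71.5%, which became 49.4 and 51.3% with each library clustered alone. No main cluster of fetal liver was named LTi-like, so those bars are at 0.

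Over all kept cells of fetal liver, genes of early B cells were the highest at E14.5. Igll1 and Vpreb1, which encode the surrogate light chain of the pre-B cell receptor, stood at 17.04 (16.4 to 17.6) and 710.4 (707 to 714) CPM (log2 fold 5.05) and at 5.87 (5.52 to 6.23) and 256 (254 to 258) CPM (4.62). Cd79a, a signalling chain of that receptor, stood at 32.2 (31.4 to 33.0) and 397 (394 to 399.9) CPM (3.46), and Vpreb3 (3.85), Vpreb2 (3.19), Ighg2b (3.15) and Ly6d (3.06) were also higher. Mcpt8, which encodes a basophil protease, stood at 3.26 (3.001 to 3.53) and 70.1 (68.9 to 71.3) CPM (3.22). Among the genes lowest at E14.5 were Cd34, a marker of progenitors, at 478 (475 to 481) and 185 (184 to 187) CPM (-1.31), the cadherin gene Cdh17 at 55.9 (54.8 to 57.0) and 12.2 (11.7 to 12.8) CPM (-1.79), and Ctla2a (-1.49), Cd33 (-1.28), Hpgds (-1.26), Cavin2 (-1.25) and Adgrl4 (-1.21). Id2, which encodes an inhibitor of E proteins needed for innate lymphoid cells, was also among these, at 241 (239 to 244) and 99.7 (98.3 to 101) CPM (-1.20).

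Of the fixed lists, the B lineage list was higher at E14.5, with 11 of 11 measured members higher and a median of 3.16, above all 10000 random lists. Its genes named the B lineage-like clusters, so it follows their share. The S phase list was slightly higher (0.18, 16 of 18 measured members higher, percentile 99.9), with Rrm2 (0.61) as an example. The stem and progenitor list was lower (-0.65, 7 of 8 measured members lower, percentile 0), with Kit (-0.64) and Hmga2 (-0.60), while Gata2 (1.59) was higher. The myeloid list was lower (-0.68, 10 of 12 measured members lower, percentile 0), with Csf1r (-1.18) and Csf3r (-0.94), against Ctsg (0.86). The list of innate lymphoid specification factors was lower (-0.40, 6 of 8 measured members lower, percentile 0), with Tox (-1.13) and Tcf7 (-0.50), against Ets1 (1.38). The LTi list of cytokines and receptors was lower in all 5 measured members (-0.41, percentile 0.160). Cytokine receptors were lower (-0.45, 6 of 8 measured members lower, percentile 0) with Flt3 (-0.59) as an example, while Il7r itself was higher at 151 (149 to 152) and 188 (186 to 190.1) CPM (0.34). The fetal program list was lower (-0.32, 7 of 8 measured members lower, percentile 0.0100) although H19 (1.32) was higher.

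Smaller medians were seen for lymphoid priming genes (0.09, percentile 87.0), with Rag1 (1.19) and Flt3 (-0.59) at its ends, and for class I antigen presentation (0.07, percentile 77.2). Glycolysis genes stood at -0.05 (percentile 1.90), NF-kB targets at -0.12 (percentile 11.7), immediate early and heat shock genes at 0.08 (percentile 83.0), and G2 and M phase genes at 0.04 (percentile 39.0). Interferon response genes lay at the median of all genes to within 0.01, at percentile 55.4. The list of homing receptors and integrins stood at -0.11 (percentile 4.32) and at 0.09 when each cell had equal weight, so it had no stable direction. It joined Cxcr6 (1.05) and Cxcr4 (0.94) with Ccr7 (-0.75) and Itgb7 (-0.38).

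Innate lymphoid progenitor-like cells of fetal liver, 773 at E13.5 and 673 at E14.5, were the class set for a closer comparison. The highest genes of this class at E14.5 were S100a9 (2.78), Igll1 (2.71), AW112010 (2.67), Skap1 (2.61), Arg1 (2.58) and Tcrg-C4 (2.49), together with Cxcr6 and Il22. Igll1, a gene of early B cells, was also higher in the median of the other fetal liver classes, as given below. Background RNA was not removed, so its fold need not belong to this class. Cxcr6, which encodes a chemokine receptor, stood at 18.2 (15.8 to 20.8) and 153 (145 to 161) CPM (2.78), and the cytokine gene Il22 at 8.84 (7.23 to 10.7) and 82.3 (76.5 to 88.6) CPM (2.66). The lowest were Gata2 (-1.85), Prss2 (-1.58), Il1r2 (-1.49), Chl1 (-1.44), Fscn1 (-1.41), Hpgds (-1.37), Flt1 (-1.23) and Cdh17 (-1.21). Id2 in this class stood at 836 (820.0 to 853) and 909.7 (889.9 to 929.9) CPM (0.13). Lymphotoxin and TNF family ligands had a median of 0.96, with Lta (1.98) and Ltb (1.02). The class mixes cells with LTi, group 1 and T cell markers, and at a finer clustering (resolution 2) S100a9 turned to -0.022, Id2 to -0.56, Lta to -0.36, Ltb to -0.44 and the ligand list to -0.44. Cxcr6 (0.053) and Il22 (0.13) were then close to the all-gene median, so most of these folds depend on how the class is drawn.

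LTi-like sub-clusters of fetal liver held 307 and 205 cells and were defined after the data had been seen. In each of them the innate lymphoid progenitor class had the highest marker level, and LTi was the next eligible class. FL10.3 had no LTi marker among its leading genes. Their mix differed between the stages, with 56, 111, 111, 24 and 5 cells at E13.5 and 25, 40, 31, 78 and 31 at E14.5 in FL10.1, FL10.2, FL10.3, FL10.7 and FL10.9. The last 2 have Il22 among their leading genes, and FL10.1 has the class II genes Cd74, H2-Aa and H2-Eb1. The folds of this class include that change of mix. The chemokine receptor gene Cxcr5 stood at 124 (113 to 136) and 125 (110.2 to 141) CPM (-0.02) at the 2 stages. Il22 was 26.3 (21.3 to 32.0) and 326 (302 to 351) CPM (3.37), and the lymphotoxin genes Lta and Ltb, whose products drive lymph node formation, were 126 (114 to 137) and 722 (686 to 759.7) CPM (2.45) and 342 (323 to 361) and 707 (672 to 744) CPM (1.01). Cxcr6 stood at 22.3 (17.7 to 27.6) and 113 (99.0 to 128) CPM (2.08) and Id2 at 1471 (1432 to 1510.0) and 1194 (1148 to 1242) CPM (-0.33). Tcrg-C1 (2.35), Rasl11a (2.69) and Jun (1.71) were higher, and Dmrt1 (-2.36), Flt1 (-2.10), Prss2 (-1.9998), Klrd1 (-1.65), Ccl5 (-1.43) and Tox (-0.46) were lower. The list of lymphotoxin and TNF family ligands had 4 of 5 measured members higher (median 1.01, percentile 100), the LTi list 11 of 14 measured members higher (0.31), and immediate early and heat shock genes 11 of 11 measured members higher (1.07). Genes of S phase were higher (0.44, 18 of 18 measured members higher) and those of G2 and M phase lower (-0.27, 15 of 18 measured members lower), and the cytotoxic and group 1 list was lower (-1.39, 5 of 5 measured members lower). B lineage genes such as Igll1 (3.88) were higher in these cells too (median 2.73), next to a median log2 fold of 2.51 for Igll1 in the other fetal liver classes.

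The second comparison asked the same of the embryonic periphery. LTi-like cells made up 34.8% (33.4 to 36.3) of kept cells at E13.5, mostly in clusters P0 and P4, and 71.5% (70.1 to 72.8) at E14.5, mostly in clusters P10, P11 and P7. Lymphoid progenitor-like cells of cluster P1 were 14.95% (13.9 to 16.1) and 0.671% (0.450 to 0.962), and innate lymphoid progenitor-like cells of cluster P5 were 15.1% (14.001 to 16.2) and 2.40% (1.97 to 2.91). Group 1 innate lymphoid or NK-like cells of cluster P2 stood at 11.9% (10.9 to 12.9) and 6.98% (6.24 to 7.78), and B lineage-like cells, mostly of clusters P3 and P6, at 10.4% (9.51 to 11.4) and 7.88% (7.10 to 8.73). P3 alone was 5.86 and 6.94% and P6 4.56 and 0.324%, so the lower share of this class comes from P6. The first leading genes were Ly6d, Siglech and Cox6a2 in P6, ahead of Cd79a and Vpreb3, and Igll1, Vpreb3 and Vpreb1 in P3. Monocyte or macrophage-like cells were 4.42% (3.81 to 5.09) and 2.34% (1.91 to 2.83), mast cell or basophil-like cells 2.47% (2.02 to 2.99) and 3.31% (2.79 to 3.88), and T cell-like cells 0.408% (0.238 to 0.653) and 0.855% (0.603 to 1.18). Of the mast cell or basophil-like clusters, P13 held 1.34 and 1.41% and P14 1.13 and 1.90%, so most of the higher share comes from P14. P14 had median depths of 1787 and 942 UMIs, and its highest marker level was that of the erythroid class, with 10 of 12 markers detected. Its name came from its leading genes, from which haemoglobin genes were left out. Of the T cell-like clusters, P12 held 16 and 17 cells and P16, of mature type, 1 and 20 cells, so the higher share comes from P16. These shares refer to the gate and the version 2 kit. LTi markers were also detected in P5 and in the unnamed cluster P9, which held 5.59 and 4.07% of cells, and with both of these the LTi-like share was 55.5 and 78.0%. Over 10 other random seeds the LTi-like share at E13.5 ranged from 36.1 to 58.3%, all above the value given, and at E14.5 from 71.5 to 77.2%. With each library clustered alone it was 49.4 and 51.3%, which nearly removes the difference between the stages, and at resolution 2 it was 48.4 and 64.9%. Other classes moved as well. With sub-clusters, group 1 innate lymphoid or NK-like cells were 2.54% at both stages, T cell-like cells 3.98 and 2.52%, the opposite order, and innate lymphoid progenitor-like cells 6.79 and 1.76%. Over 10 other seeds the last class held at most 0.648 and 1.09%, and with each library clustered alone 22.2% at E14.5. No cells at E13.5 were named lymphoid progenitor-like with all libraries clustered together or with cell-cycle genes kept.

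Over all kept cells of periphery, Id2 stood at 405 (399 to 410.4) and 1527 (1515 to 1539) CPM (log2 fold 1.68) at E13.5 and E14.5. Hk2, which encodes a hexokinase, stood at 17.7 (16.5 to 18.9) and 100.2 (97.2 to 103) CPM (1.99), and the chemokine receptor genes Cxcr6 and Ccr6 at 73.0 (70.6 to 75.4) and 259 (254 to 264) CPM (1.53) and 29.1 (27.7 to 30.7) and 80.6 (77.9 to 83.4) CPM (1.099). The mast cell chymase gene Cma1 was highest of all (2.08), and others near the top were Scand1 (1.93), Atp5k (1.86), the Notch ligand gene Dll1 (1.84), Asb2 (1.82) and Ccdc184 (1.82). Il7r, the gene of the sorted receptor, stood at 213 (209 to 217) and 397 (391 to 403) CPM (0.66). Lowest at E14.5 were the heat shock gene Hspa1a at 53.0 (51.0 to 55.0) and 0.741 (0.503 to 1.05) CPM (-3.56), the cytokine gene Il1b at 59.3 (57.2 to 61.4) and 3.04 (2.53 to 3.61) CPM (-3.23), the chemokine gene Ccl4 at 287 (283 to 292) and 41.8 (39.8 to 43.8) CPM (-2.87), and Gstp1 (-2.84), Crem (-2.57), Siglech (-2.57), Hmga1 (-2.54) and Cox6a2 (-2.50). Progenitor genes were also lower, with Ly6d (-2.41), Cd34 (-2.14) and Flt3, which stood at 37.2 (35.6 to 38.9) and 6.76 (6.00 to 7.60) CPM (-2.07).

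The LTi list was higher at E14.5 in all 14 measured members (median 0.58, percentile 100), with Il23r, a cytokine receptor gene, at 8.31 (7.53 to 9.14) and 31.4 (29.7 to 33.1) CPM (1.22). The list of lymphotoxin and TNF family ligands had 4 of 5 measured members higher (0.57, percentile 99.8), with Ltb at 1007 (999 to 1016) and 1931 (1917 to 1944) CPM (0.71) and Lta at 166 (162 to 169) and 305 (299.9 to 311) CPM (0.63), and with Tnfsf11 (-0.09). Innate lymphoid specification factors were higher (0.45, 11 of 12 measured members higher, percentile 100), with Maf (1.04), Gata3 (0.47) and Tcf7 (0.27). The list of cytokine receptors was higher (0.33, percentile 99.9), with Il27ra (1.06), and homing receptors had a median of 0.16 (percentile 94.8), with Ccr9 (-1.86) the lowest. The B lineage list was higher (0.37, 10 of 11 measured members higher), with Vpreb1 (0.92) as an example. The share of B lineage-like cells was lower, but only through cluster P6, while cluster P3, led by Igll1, Vpreb3 and Vpreb1, had a higher share. Cell cycle lists stood at 0.13 for S phase (percentile 98.8) and 0.21 for G2 and M phase (percentile 99.9), class I antigen presentation at 0.30 (percentile 99.5), and immediate early and heat shock genes at 0.20 (percentile 99.1), where Jun (1.41) and Hspa1a pointed opposite ways.

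Lists of other cell types were mostly lower at E14.5 in periphery. Lymphoid priming genes stood at -0.55 (7 of 10 measured members lower, percentile 0), myeloid genes at -0.86 (11 of 13 measured members lower, percentile 0), with C1qb (-1.52) as an example, and cytotoxic and group 1 genes at -0.70 (4 of 6 measured members lower), with Klrd1 (-1.499) and Ccl5 (-1.34). Interferon response genes stood at -0.83 (6 of 7 measured members lower, percentile 0), with Isg15 (-1.58) and Bst2 (-0.87), and stem and progenitor genes at -0.33 (percentile 0.630). Erythroid genes were lower in all 6 measured members (-2.61), with Hbb-bs (-3.89) and Hbb-y (-3.08). Glycolysis genes had a median of -0.21 (percentile 33.6) between Hk2 (1.99) and Eno1 (-1.03), the fetal program -0.18 (percentile 9.88), and NF-kB targets lay within 0.01 of all genes, between Nfkb2 (0.99) and Nfkb1 (-1.09). T cell receptor genes had a median of -0.06, which turned to 0.10 with no minimum level, and joined Tcrg-C1 (1.30) with Cd3g (-1.14).

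Within the LTi-like cells of periphery, 1450 at E13.5 and 3092 at E14.5, several of the genes that name the class were close to the all-gene median. Ltb stood at 1936 (1914 to 1958) and 2528 (2509 to 2547) CPM (0.16), and Cxcr5, Lta and Tcf7 had folds of 0.19, 0.10 and -0.07. Id2 was higher at E14.5, at 577 (565 to 589) and 1856 (1839.5 to 1872) CPM (1.45). So were Jun, part of the AP-1 factor, at 164 (158 to 171) and 703 (693 to 713) CPM (1.84), the cytokine gene Tnf at 16.9 (14.97 to 19.1) and 72.3 (69.2 to 75.6) CPM (1.59), Hk2 at 25.8 (23.4 to 28.5) and 125 (121 to 129) CPM (1.85) and Cxcr6 at 160.3 (154 to 167) and 325 (318 to 332) CPM (0.77). Scand1 (1.98), Atp5k (1.65), Asb2 (1.61), Yipf4 (1.57), Cox17 (1.52), Tcrg-C1 (1.29), Csf2 (1.28), Ccr6 (0.72) and Il23r (0.66) were higher as well. Lowest were Hspa1a at 34.3 (31.5 to 37.4) and 0.434 (0.224 to 0.757) CPM (-3.08), Crem, a transcription factor gene of the cAMP response, at 188 (182 to 195) and 23.3 (21.5 to 25.2) CPM (-3.001), and Gstp1 (-2.85), Hist1h2ap (-2.55), Hmga1 (-2.36), Ccdc85b (-2.02), Litaf (-1.998) and Fosl2 (-1.83). The interleukin 17 genes were lower, with Il17a (-0.54) and Il17f (-0.34). The surface genes Cd4 (0.40) and Il7r (0.32) were higher and Tnfsf11 (-0.17) lower.

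In these cells the LTi list had 11 of 14 measured members higher and a median of 0.17 (percentile 99.5), and all of its genes but Csf2 and Ahr also served to name the class. Adding cluster P5 to the class moved this median to 0.32, and adding P9 to 0.11. Innate lymphoid specification factors (0.24, 8 of 12 measured members higher) included Runx3 (0.90) and Pdcd1 (-0.45), and homing receptors (0.20, 8 of 10 measured members higher), cytokine receptors (0.20, 8 of 9 measured members higher) and lymphoid priming genes (0.32, 5 of 7 measured members higher), among them Sox4 (0.76), lay at percentiles of 98.1 or more. Immediate early and heat shock genes stood at 0.37 (8 of 13 measured members higher, percentile 100), class I antigen presentation at 0.15 and lymphotoxin and TNF family ligands at 0.16 (percentile 93.4). NF-kB targets (-0.13), T cell receptor genes (-0.18), glycolysis (-0.16), the fetal program (-0.02), interferon response (0.04) and S phase (-0.03) lay between the 20th and 80th percentiles. The G2 and M phase list was lower (-0.15, 17 of 18 measured members lower), but turned to 0.20 at resolution 0.5, 0.32 at resolution 2, 0.07 with sub-clusters and 0.17 with P5, so its direction is open.

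Part of these stage differences was shared by other classes of the same libraries. Before the all-gene median is taken off, Id2 had a log2 fold of 1.68 in LTi-like cells and a median of 1.44 in the 4 other classes compared (B lineage, group 1, mast cell or basophil and monocyte or macrophage-like cells). Scand1 (2.21 and 2.10), Hk2 (2.07 and 1.73), Atp5k (1.87 and 1.94) and Gstp1 (-2.62 and -2.86) were likewise close. Background RNA was not removed, and for genes high in LTi-like cells, such as Id2, it would move the other classes in the same direction. Median depths at E13.5 and E14.5 were 12469 and 1366 UMIs in monocyte or macrophage-like cells and 12668 and 1736 in mast cell or basophil-like cells. Background RNA can therefore take a larger part of the UMIs of these classes at E14.5. Genes highest in LTi-like cells relative to the other classes were Ramp1 (difference 1.82), Ccl5 (1.75), Tnf (1.67), Jun (1.35), Sox4 (1.28), Tsc22d1 (1.25), Tcrg-C1 (1.23) and Tnfrsf9 (1.23). Lowest were Cxcl10 (-1.66), H2-Aa (-1.23), S100a6 (-1.21), Serpina3f (-1.17), Litaf (-1.07), Il22 (-1.05, from 0.168 in LTi-like cells and 1.22 in the others), Pld4 (-1.003) and Ltb4r1 (-0.99). Both rankings are of differences, so a gene can stand high without being higher at E14.5 in LTi-like cells, where the other classes fell more. The comparison with other classes was added after the data had been seen, and classes were included for a gene only where they measured it. Innate lymphoid progenitor-like cells were left out of it, although they had enough cells.

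**Figure D2:**
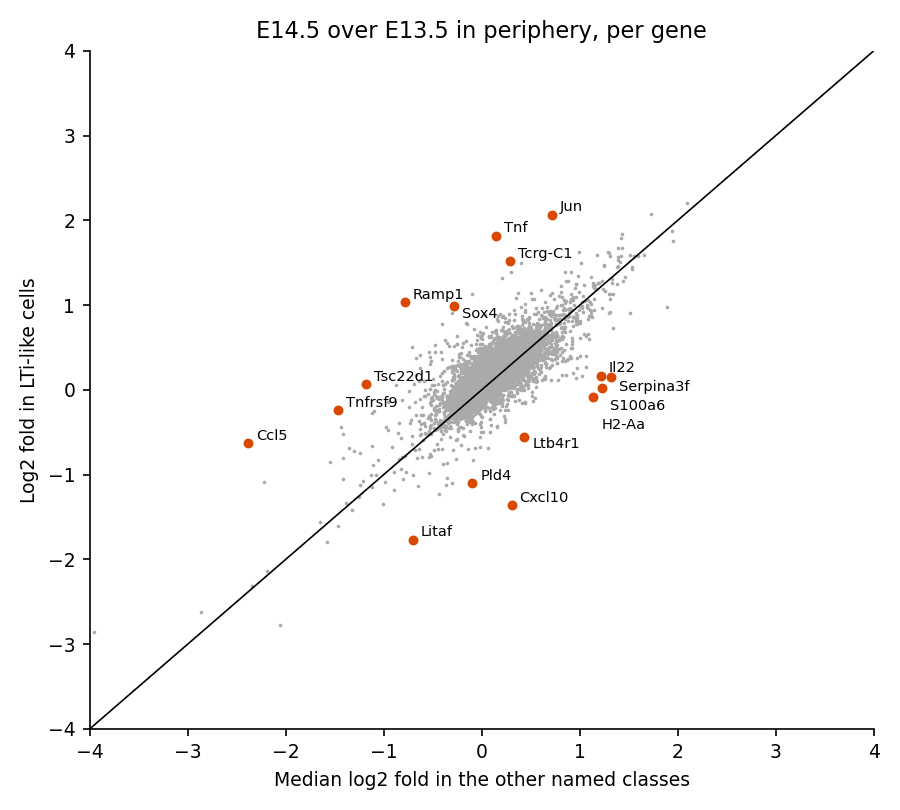
Log2 fold of E14.5 over E13.5 in LTi-like cells of periphery (vertical axis) against the median of the other named classes of the same libraries (horizontal axis) for 4893 genes, before the all-gene median is taken off. Orange points are the 8 genes with the highest and the 8 with the lowest difference, among them Ramp1 at 1.82 and Cxcl10 at -1.66.

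The share of cells with a UMI of LTi genes was compared at equal depth, after thinning to 3000 UMIs. Cxcr6 was found in 0.438% (0.316 to 0.592) of fetal liver cells at E13.5 and 2.04% (1.78 to 2.33) at E14.5, and in 19.5% (18.2 to 20.7) and 50.6% (49.1 to 52.2) of periphery cells. In B lineage-like cells, taken as background, Cxcr6 was found in 0% (0 to 0.596) and 0.0479% (0.00580 to 0.173) of fetal liver cells and in 0% (0 to 0.850) and 2.13% (0.860 to 4.33) of periphery cells. Median depths before thinning were 18400.0, 16031.5, 11283 and 8756.5 UMIs in all cells and 9364, 15021, 13104 and 18502 in B lineage-like cells, and 193, 402, 127 and 221 of all cells were too shallow. In B lineage-like cells 142, 256, 2 and 12 were too shallow. Without thinning Cxcr6 was found in 0.911, 3.01, 37.3 and 72.5% of all cells and in 0, 0.0903, 0.691 and 7.04% of B lineage-like cells.

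Id2 was found in 29.4% (28.5 to 30.3) and 14.1% (13.47 to 14.8) of fetal liver cells and in 58.3% (56.8 to 59.9) and 89.0% (88.0 to 89.9) of periphery cells. Flt3, which encodes a receptor of progenitors, was found more often in fetal liver, with 43.7% (42.8 to 44.7) and 26.9% (26.0 to 27.7) in fetal liver and 7.97% (7.16 to 8.85) and 1.17% (0.864 to 1.55) in periphery. Il7r was found in 34.4, 42.0, 45.1 and 66.5% of cells in the same order of libraries, Ltb in 11.6, 9.29, 71.8 and 89.3%, and Tcf7 in 8.32, 5.93, 44.1 and 57.5%. Ptprc, which encodes the sorted CD45, was found in 35.2, 25.7, 17.1 and 19.2%, and Adgre1, which encodes F4/80, in 0.616, 1.63, 1.63 and 1.32%. In B lineage-like cells, again in this order, Id2 was found in 13.8, 2.30, 7.87 and 13.4%, Flt3 in 31.0, 12.3, 15.3 and 4.26%, Il7r in 50.1, 45.0, 35.9 and 28.3%, Ltb in 9.24, 6.23, 15.7 and 22.5%, Tcf7 in 2.92, 1.15, 1.39 and 1.82%, Ptprc in 29.3, 14.95, 14.4 and 10.0%, and Adgre1 in 0, 0.0479, 0 and 0.608%. Within LTi-like sub-clusters Cxcr6 was found in 5.65% (3.32 to 8.89) and 28.6% (22.4 to 35.6) of fetal liver cells and 33.4% (31.2 to 35.6) and 58.0% (56.3 to 59.8) of periphery cells.

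**Figure D3:**
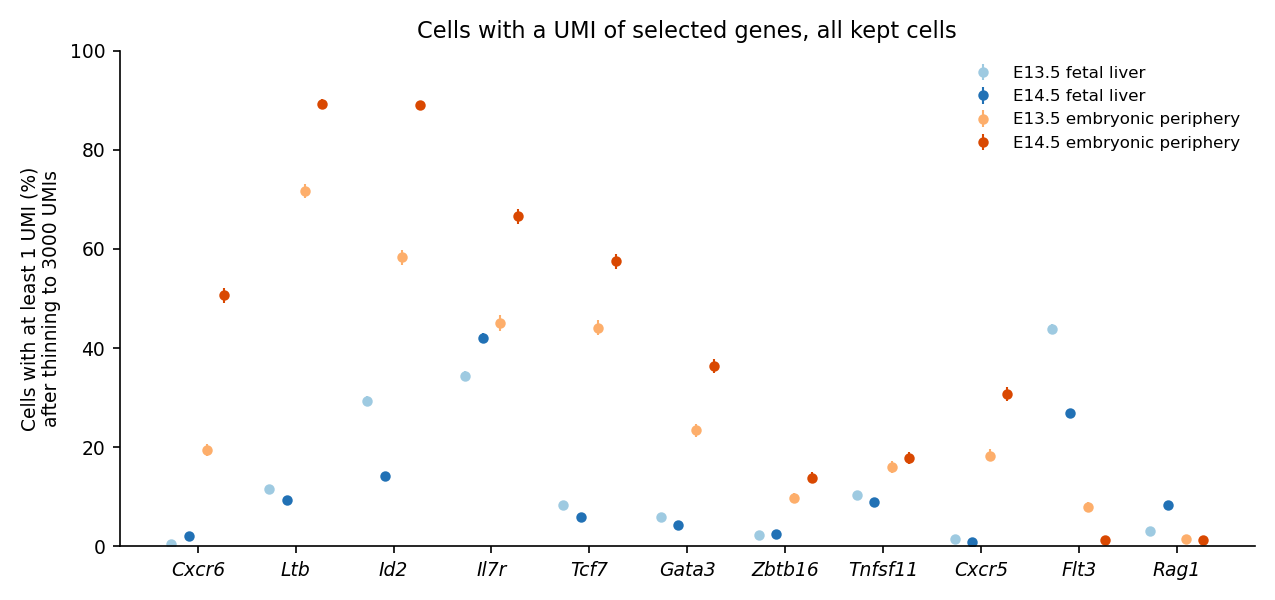
Share of kept cells (percent, vertical axis) with at least 1 UMI of 11 genes after thinning to 3000 UMIs, in the 4 libraries, with exact 95% intervals that cover counting error only. Cxcr6 stands at 0.438 and 2.04% in fetal liver and at 19.5 and 50.6% in periphery.

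The third comparison set periphery against fetal liver at each stage, with tissue and kit inseparable. Ltb stood at 42.0 (41.0 to 42.9) and 1010.4 (1002 to 1019) CPM at E13.5 (log2 fold 4.84) and 36.4 (35.5 to 37.3) and 1936 (1923 to 1949.8) CPM at E14.5 (5.72) in fetal liver and periphery. Id2 stood at 242 (239.7 to 244) and 406 (401 to 412) CPM (1.14) and 99.95 (98.5 to 101) and 1532 (1520.0 to 1544) CPM (4.04). At E13.5 and E14.5 the folds of other genes higher in periphery were 5.28 and 5.86 for Prr29, 5.05 and 5.16 for Srp54c, 4.94 and 5.90 for Cd82, 4.97 and 4.44 for Arg1, 4.64 and 5.25 for Rasl11a, and 4.70 and 4.83 for Hmgn3. Il22 was higher as well (7.29 and 7.49), a value left uncertain by its close copy Iltifb. Lowest in periphery were Fau, whose product is cleaved into a ubiquitin-like protein and a ribosomal protein, at 3211 (3203 to 3219) and 12.9 (11.9 to 13.9) CPM (-7.08) and 3340.2 (3332 to 3349) and 19.6 (18.3 to 21.0) CPM (-6.92), Atp5g2 (-6.46 and -6.12), Tfdp1 (-5.28 and -5.78), Lsm7 (-5.27 and -5.40), Alyref (-4.56 and -4.51), Klf2 (-4.61 and -4.41), Pgk1 (-4.45 and -6.201) and Timm8a1 (-4.11 and -5.12).

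The LTi list was higher in periphery at E13.5 (2.77, 11 of 12 measured members higher) and at E14.5 (3.17, 14 of 14 measured members higher), and the E13.5 median was 1.65 with no minimum level. Innate lymphoid specification factors (2.10 and 2.93), lymphotoxin and TNF family ligands (1.80 and 2.39), NF-kB targets (1.88 and 2.28), T cell receptor genes (3.13 and 2.60) and cytotoxic and group 1 genes (3.24 and 2.42) were higher too. Examples at E13.5 and E14.5 were Cxcr6 (4.07 and 4.56), Gata3 (2.25 and 2.94), Lta (4.19 and 3.57) and Nfkbia (4.67 and 3.51). Lymphoid priming genes (-1.68 and -2.13), with Flt3 at -1.86 and -3.32 and Sox4 at -3.07 and -3.20, stem and progenitor genes (-1.72 and -1.27) and the fetal program (-0.72 and -0.79) were lower. The B lineage list was higher in periphery at E13.5 (2.14, 9 of 9 measured members higher) and lower at E14.5 (-0.85, 10 of 11 measured members lower). The myeloid list stood at -0.13 at E13.5 and 0.19 at E14.5, and its E13.5 median turned to 0.97 with equal weight for each cell, 0.71 without mitochondrial and ribosomal genes, 0.24 with no minimum level and 0.59 with median-of-ratios scaling. Glycolysis genes stood at 0.22 and -0.10, the first of which turned to -0.18 with no minimum level.

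Among LTi-like sub-clusters, 307 and 205 cells of fetal liver were set beside 1816 and 3179 of periphery, a comparison added after the data had been seen. The fetal liver sub-clusters had the innate lymphoid progenitor class at the highest marker level, while the main LTi-like clusters of periphery had LTi. Folds of progenitor markers such as Tcf7, Tox and Nfil3 cannot be separated from this difference in the cells. Cxcr5 had folds of 0.37 at E13.5 and 0.45 at E14.5, and Il7r of 0.05 and 0.09. Ltb was higher in periphery, at 342 (324 to 362) and 1850.3 (1831 to 1869.7) CPM (2.81) and 709 (673 to 746) and 2516 (2497 to 2534) CPM (1.97), as was Cxcr6 (2.82 and 1.63), and Tcf7, a transcription factor gene of early lymphocytes, was lower at 1439 (1400.3 to 1478) and 392 (383 to 401) CPM (-1.47) and 1497 (1445 to 1551) and 429 (421 to 436) CPM (-1.64). Id2 was lower in periphery at E13.5, at 1474 (1435 to 1513) and 591 (579.9 to 602) CPM (-0.92), and higher at E14.5, at 1197 (1150.3 to 1245) and 1877 (1861 to 1893) CPM (0.80), and Lta had the opposite order (1.72 and -0.65). Il22 (6.07 and 2.82), Dlk1 (3.16 and 1.99), Cd83 (3.68 and 2.83) and Hk2 (1.68 and 2.85) were higher in periphery, and Sox4 (-3.21 and -2.45), Flt3 (-2.41 and -2.54), Ccr9 (-2.15 and -2.55), Nfil3 (-2.15 and -1.76), Tox (-1.31 and -0.86) and Tnf (-1.09 and -1.15) were lower. Fau (-7.35 and -7.18), Atp5g2 (-6.58 and -6.11), Taf10 (-5.07 and -4.55) and Jund (-4.25 and -4.66) were lower, and Srp54c (5.08 and 4.96), Fdx1l (4.85 and 4.26), Tonsl (4.81 and 4.64) and Raver1 (4.05 and 4.02) higher.

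A difference of kit that is equal in all classes drops out when the median fold of the other classes present in both tissues is taken off. For Fau this difference was 0.01 at E13.5 and -0.06 at E14.5, and for Alyref -0.02 and -0.04, so their folds were close to the median of the other classes. Relative to the other classes, LTi-like cells of periphery were higher at E13.5 in Il22 (2.74), Dlk1 (1.98), Ung (1.65), Rasl11a (1.43), Hk2 (1.37) and Ccr7 (1.21), and lower in Ccl5 (-4.07), Cd3g (-3.92), Ccr9 (-2.92), Tnf (-2.66) and Tcf7 (-1.94). At E14.5 they were higher in Hk2 (1.15), Nfkb2 (1.12), Relb (0.97) and Pfkp (0.90), and lower in Vpreb1 (-3.25), Cd3g (-2.61), Cd24a (-2.59), H19 (-2.26) and Tcf7 (-1.53). These are differences of folds, so a low value can come from a higher fold in the other classes, with little change in LTi-like cells. Background RNA was not removed here either. For Ltb the difference was 0.57 and 0.06. The LTi list in these cells stood at 0.88 (12 of 14 measured members higher) and 0.94 (11 of 14 measured members higher), next to differences from the other classes of 0.11 and -0.65. Of the other lists, NF-kB targets stood at 1.14 and 0.73 (differences from the other classes -0.14 and 0.60), class I antigen presentation at 0.76 and 0.49 (0.087 and 0.19), and innate lymphoid specification factors at -0.55 and -0.23 (-0.18 and 0.022). S phase stood at 0.71 and 0.15 (0.67 and 0.067), G2 and M phase at -0.71 and -0.31 (-0.22 and 0.18), interferon response at -0.58 and -0.89 (-1.24 and -0.95), and lymphoid priming at -1.37 and -1.504 (-0.48 and -0.82).

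**Figure D4:**
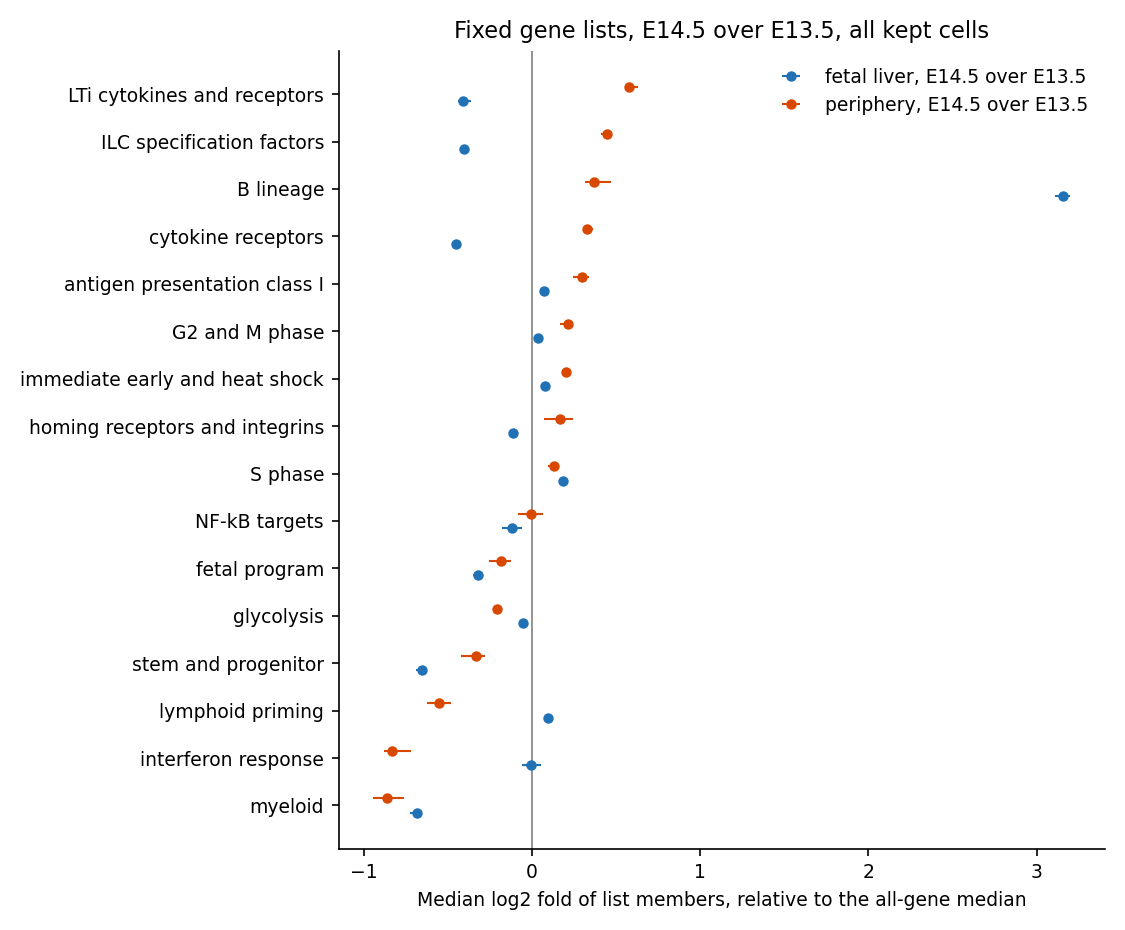
Median log2 fold of E14.5 over E13.5 (horizontal axis) of 16 fixed gene lists (vertical axis), relative to the median of all measured genes, over all kept cells of fetal liver and of periphery. The B lineage list stands at 3.16 in fetal liver, and the LTi list at -0.41 in fetal liver and 0.58 in periphery.

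The genes at the centre of these comparisons lie as follows on GRCm38/mm10. Il7r (ENSMUSG00000003882) lies on chromosome 15 at 9505788 to 9530176, and Id2 (ENSMUSG00000020644) on chromosome 12 at 25093799 to 25097140. Ltb (ENSMUSG00000024399), Tnf (ENSMUSG00000024401) and Lta (ENSMUSG00000024402) lie on chromosome 17 at 35194439 to 35196320, 35199381 to 35202007 and 35203165 to 35205351. Cxcr6 (ENSMUSG00000048521) lies on chromosome 9 at 123806475 to 123811760, Flt3 (ENSMUSG00000042817) on chromosome 5 at 147330741 to 147400489, and Hk2 (ENSMUSG00000000628) on chromosome 6 at 82725025 to 82774454. Igll1 (ENSMUSG00000075370) and Vpreb1 (ENSMUSG00000059305) lie on chromosome 16 at 16860671 to 16863985 and 16868403 to 16870843. The annotation lists each of them as a protein-coding gene.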

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

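All comparisons in this part were chosen only after the results had been seen. Id2 was flagged for a difference between groups, since its stage folds had opposite signs in the tissues. It was not the only such gene, since Ly6d, as given above, was higher at E14.5 in fetal liver and lower in periphery. Id2 over all kept cells was lower at E14.5 in fetal liver (log2 fold -1.20) and higher in periphery (1.68), a difference of 2.88. The difference was not tested, since each group has 1 library, and the share of LTi-like and B lineage-like cells differed between the libraries as well.

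The stage folds of LTi-like cells in periphery, Id2 among them, were weighed against technical explanations. The folds below are given before the all-gene median is taken off. That median was 0.23 in LTi-like cells, which favours genes higher at E14.5. Of 143 genes that were at least 2-fold different and well enough counted, 131 (median size 1.24) were measured in at least 2 other classes and entered the tests. The other 12, of which 10 were higher at E14.5, were not tested, so nothing below refers to them. A difference between the libraries that the other classes share may account for much of them, since the median fold of the other classes in the same direction was 1.11 (quartiles 0.818 to 1.38). For the 34 genes no higher in LTi-like cells than in the median other class at E14.5 it was 1.04 (0.660 to 1.32). For the 18 of these that were higher at E14.5, how much background RNA of LTi-like cells adds is not known, since its share was not estimated. For the 16 lower ones background RNA stays open too, since their levels at E13.5 were not compared. For the other 97 (1.13, 0.844 to 1.39), Id2 among them, background RNA stays open. Another mix of LTi-like clusters could be tested only within cluster P4. The folds there had a median of 1.18 (0.859 to 1.5004), so folds of this size occurred in P4 without a change in the mix of clusters. P4 held 486 of 1450 and 82 of 3092 LTi-like cells at E13.5 and E14.5, and its cells helped to choose the genes. For the other LTi-like clusters, each with fewer than 50 cells at a stage, a change of mix stays open. B lineage-like cells of fetal liver had a median of 0.00422 (-0.310 to 0.273) for 101 of the genes. For the typical gene this argues against a stage effect shared with that class. Its mix differed between the stages, with 386 of 759 and 369 of 4429 cells in FL13. Only LTi-like sub-clusters of fetal liver were compared besides, so a stage effect common to both tissues stays open for other lineages. These sub-clusters, whose mix also differed, had a median of 0.171 (-0.000897 to 0.542) for 125 genes. For the typical gene this argues against an effect common to LTi-like cells of both tissues. Such an effect stays open for the 25 of these genes with at least 50% of the periphery fold in fetal liver, Jun and Tcrg-C1 among them. Whether the shared part comes from library handling or from development of the whole periphery could not be told apart with 1 library per stage.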

How the results depend on the processing

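The sub-clusters, the other seeds, the additions of clusters P5 and P9 and the comparison with other classes were chosen only after the results had been seen, and the other settings were fixed beforehand. No paired analysis was possible because each group has 1 library. Settings with no cell filter, no minimum CPM, called doublets kept or equal weight for each cell were run for folds over all kept cells only, not within classes. A turned sign was counted only where the counting interval of the reported value excluded 0, so other sign changes are not in these counts. Of 5098 alternative values for 852 folds of single genes, 1375 lay outside the counting interval of the reported value and 3661 inside it. The remaining 62 had the opposite sign, out of 4603 values whose reported interval excluded 0. For 163 list medians, 26 of the 882 alternative values whose reported interval excluded 0 had the opposite sign, and 338 of all 973 lay outside the interval. Shares of cells with a UMI lay outside it in 168 of 252 values and class shares in 158 of 281. Clustering is the weakest step. The partition can move with floating-point rounding, and in periphery at E13.5 the LTi-like share over 10 other seeds ranged from 36.1 to 58.3% with a median of 52.6%, so the reported 34.8% lies below all of them. With cluster P5 added it was 49.9%, and with each library clustered alone the stages hardly differed. In fetal liver the innate lymphoid progenitor-like class holds cells of several kinds, and most of the signs that turned belong to it. Naming clusters against the mean over clusters, or with no second eligible class, was tried on the data and not kept, and gave no values here. Depth limits shares of cells with a UMI, as the values without thinning show.

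Class shares stood at 7.77 and 40.7% for B lineage-like cells and 34.8 and 71.5% for LTi-like cells in the reported clustering. Without a cell filter, B lineage-like cells of fetal liver were 8.85% at E13.5 and 42.4% at E14.5 and LTi-like cells of periphery were 63.6% at E14.5. With at least 1000 genes and at most 5% mitochondrial UMIs, B lineage-like cells of fetal liver were 4.02% at E13.5 and 42.0% at E14.5 and LTi-like cells of periphery were 56.0% at E13.5 and 79.5% at E14.5. With marked doublets kept, B lineage-like cells of fetal liver were 6.202% at E13.5 and 38.9% at E14.5 and LTi-like cells of periphery were 39.8% at E13.5 and 74.5% at E14.5. With each library clustered alone, B lineage-like cells of fetal liver were 4.001% at E13.5 and LTi-like cells of periphery were 49.4% at E13.5 and 51.3% at E14.5. With all 4 libraries clustered together, B lineage-like cells of fetal liver were 5.63% at E13.5 and 36.4% at E14.5 and LTi-like cells of periphery were 57.0% at E13.5 and 79.0% at E14.5. With cell-cycle genes kept for clustering, B lineage-like cells of fetal liver were 14.1% at E13.5 and 49.6% at E14.5 and LTi-like cells of periphery were 53.4% at E13.5 and 76.8% at E14.5. At resolution 0.5, B lineage-like cells of fetal liver were 5.41% at E13.5 and 36.6% at E14.5 and LTi-like cells of periphery were 55.0% at E13.5 and 78.5% at E14.5. At resolution 2, B lineage-like cells of fetal liver were 5.05% at E13.5 and 44.4% at E14.5 and LTi-like cells of periphery were 48.4% at E13.5 and 64.9% at E14.5. At the highest of 10 other seeds, B lineage-like cells of fetal liver were 14.48% at E13.5 and 49.7% at E14.5 and LTi-like cells of periphery were 58.3% at E13.5 and 77.2% at E14.5. With sub-clusters of mixed clusters, LTi-like cells of periphery were 43.6% at E13.5 and 73.5% at E14.5. With cluster P5 added to the LTi-like class, LTi-like cells of periphery were 49.9% at E13.5 and 73.9% at E14.5. With cluster P9 added, LTi-like cells of periphery were 40.4% at E13.5 and 75.6% at E14.5. With clusters P5 and P9 added, LTi-like cells of periphery were 55.5% at E13.5 and 78.0% at E14.5. The cause of these differences was not tested.

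In the following each pair gives the reported value and that under the setting named. At resolution 0.5, values between stages in LTi-like cells of periphery were the G2 and M phase list (-0.15 to 0.20) and Tox (0.13 to -0.038). Between stages in innate lymphoid progenitor-like cells of fetal liver it gave the LTi list (0.20 to -0.26), innate lymphoid specification factors (0.28 to -0.070), homing receptors and integrins (0.14 to -0.11), Il7r (0.14 to -0.26), Id2 (0.13 to -0.22), Nkg7 (0.29 to -0.059) and Ccl5 (0.24 to -0.22). At resolution 2, values between stages in LTi-like cells of periphery were the G2 and M phase list (-0.15 to 0.32), Zbtb16 (0.16 to -0.022) and Tox (0.13 to -0.087). Between stages in innate lymphoid progenitor-like cells of fetal liver it gave lymphotoxin and TNF family ligands (0.96 to -0.44), cytokine receptors (0.55 to -0.15), lymphoid priming (-0.11 to 0.10), cytotoxic and group 1 genes (0.998 to -0.15), stem and progenitor genes (-0.39 to 0.095), NF-kB targets (0.36 to -0.16), glycolysis (0.17 to -0.10), S100a9 (2.78 to -0.022), Id2 (0.13 to -0.56), Lta (1.98 to -0.36), Ltb (1.02 to -0.44), Tcf7 (-0.15 to 0.21) and Il17f (-0.81 to 0.034). Further values there were Nfil3 (-0.35 to 0.076), Cxcr3 (1.70 to -0.24), Il12rb1 (1.35 to -0.041), Sox4 (-0.45 to 0.12), Klrk1 (2.35 to -0.0033), Ncr1 (1.75 to -0.0033), Ccl5 (0.24 to -0.35), S100a8 (1.95 to -0.26), Mpo (-0.68 to 0.14), Prtn3 (-0.72 to 0.15), Rrm2 (0.43 to -0.11), Mki67 (0.11 to -0.18) and Birc5 (0.097 to -0.17). Further values there were Pkm (0.39 to -0.097) and H2-D1 (1.18 to -0.0058). With sub-clusters of mixed clusters, values between stages in LTi-like cells of periphery were the G2 and M phase list (-0.15 to 0.067). Between stages in innate lymphoid progenitor-like cells of fetal liver it gave the LTi list (0.20 to -0.0087), lymphoid priming (-0.11 to 0.050), NF-kB targets (0.36 to -0.11), interferon response genes (0.47 to -0.015), glycolysis (0.17 to -0.0096), S100a9 (2.78 to -0.029), Ltb (1.02 to -0.24), Itga4 (-0.45 to 0.040), Tcf7 (-0.15 to 0.27), Il17f (-0.81 to 0.0082), Flt3 (-0.64 to 0.050), Nfil3 (-0.35 to 0.41) and Ccl5 (0.24 to -0.36). Further values there were S100a8 (1.95 to -0.25), Dlk1 (0.74 to -0.090), Traf1 (0.84 to -0.24), Mki67 (0.11 to -0.22), Birc5 (0.097 to -0.17), Jun (1.02 to -0.046), H2-K1 (1.45 to -0.055) and H2-D1 (1.18 to -0.097). With cluster P5 added to the LTi-like class, values between stages in LTi-like cells of periphery were the LTi list (0.17 to 0.32), the G2 and M phase list (-0.15 to 0.17) and Tox (0.13 to -0.039). With cluster P9 added, values between stages in LTi-like cells of periphery were the LTi list (0.17 to 0.11). With equal weight for each cell, values between stages in fetal liver were homing receptors and integrins (-0.11 to 0.091) and the B lineage list (3.16 to 3.01). Between stages in periphery it gave the LTi list (0.58 to 0.53), Gzma (0.22 to -0.36) and Ifi203 (-0.18 to 0.078). Between tissues at E13.5 it gave the myeloid list (-0.13 to 0.97). Between tissues at E14.5 it gave the LTi list (3.17 to 3.33), Vpreb1 (0.15 to -0.68) and H19 (0.60 to -0.069). With CPM that left out mitochondrial, ribosomal and haemoglobin genes, values between stages in fetal liver were the B lineage list (3.16 to 3.38). Between tissues at E13.5 it gave the LTi list (2.77 to 2.85) and the myeloid list (-0.13 to 0.71). Between tissues at E14.5 it gave the LTi list (3.17 to 3.36). With 1 CPM added in place of 5, values between stages in fetal liver were the B lineage list (3.16 to 3.62). Between tissues at E13.5 it gave the LTi list (2.77 to 3.64). Between tissues at E14.5 it gave the LTi list (3.17 to 4.58). Between stages in LTi-like cells of periphery it gave Rag1 (-0.15 to 0.11). With no minimum CPM, values between stages in periphery were the LTi list (0.58 to 0.76), T cell receptor genes (-0.060 to 0.100), Tnfsf11 (-0.087 to 0.11), Itgb7 (-0.10 to 0.092), Ptprc (-0.15 to 0.043), Ifi203 (-0.18 to 0.016) and Psmb8 (-0.13 to 0.059). Between tissues at E13.5 it gave the LTi list (2.77 to 1.65), the myeloid list (-0.13 to 0.24), glycolysis (0.22 to -0.18), Runx3 (0.18 to -0.22), Cdc20 (0.37 to -0.029), Tap1 (0.32 to -0.073) and Tap2 (0.23 to -0.17). Between tissues at E14.5 it gave the LTi list (3.17 to 3.01) and Vpreb1 (0.15 to -0.018). With median-of-ratios scaling, values between tissues at E13.5 were the LTi list (2.77 to 2.60) and the myeloid list (-0.13 to 0.59). Between tissues at E14.5 it gave the LTi list (3.17 to 3.13). Between stages in LTi-like cells of periphery it gave Rag1 (-0.15 to 0.081). Between tissues at E13.5 in LTi-like sub-clusters it gave Rag1 (0.39 to -0.039). With thinning to 1500 UMIs, Cxcr6 was found in 0.278, 1.31, 10.8 and 33.2% of the cells. Without thinning, Cxcr6 was found in 0.911, 3.01, 37.3 and 72.5% of the cells. With no minimum CPM the all-gene median itself moves, from 0.23 to 0.03 between stages in periphery and from -0.41 to -0.01 between tissues at E13.5, which accounts for the single genes whose sign turned there by construction. For lists the setting also changes which members count, and the myeloid list moved against the shift. With fewer or more UMIs per cell the share of cells with a UMI falls or rises by construction. For the other values the cause was not tested.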

Other observations

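All tests in this part were chosen only after the results had been seen, except that of GC content, which was written down before its value was known. Clusters P16 and P17 of periphery at E14.5 held 20 T cell-like and 27 B cell-like cells of mature type, with Trac, Cd3d and Cd3e among the leading genes of P16 and Igkc, Ighm and Ms4a1 among those of P17. The class I genes H2-K1 and H2-D1 together stood at 4538 CPM (4217 to 4878) in these 47 cells and 1033 CPM (1023 to 1043) in the other cells of the library. Genes of S, G2 and M phase stood at 1152 CPM (992 to 1329) and 6206 CPM (6182 to 6230.1), and Xist at 1324 CPM (1153 to 1513) and 635 CPM (628 to 643). A different cluster, P12, held 17 immature T cell-like cells at this stage with a fetal program level of 1904 CPM (1777 to 2037), and in these no Y-linked UMI was found where 26.6 would match the other cells.

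Maternal blood is a candidate source of the cells of P16 and P17. Il7r stood at 499 CPM (337 to 713) in P16 but at 19.5 CPM (2.37 to 70.6) in P17, with a UMI in only 2 of its 27 cells, so how P17 came through a gate on IL7Ra is not explained. Only 1 Y-linked UMI was found in P16 and P17 (6.16 CPM, 0.156 to 34.3, against 60.5 CPM in the other cells), a single UMI with a wide interval. Xist had a UMI in 45 of the 47 cells (95.7%), against 54.8% of the other cells, although their median depth was higher (8543 against 3696 UMIs). Nearly all of the 47 cells therefore look female. That would hold for maternal cells and for cells of a female embryo alike, so the source stays open. Mature cells of a female embryo stay open too. The fetal program list stood at 73.9 CPM (38.2 to 129) in these cells, below the lowest bound of 183 CPM in the other clusters compared, but 0 of those clusters held T or B type cells with as few cell cycle UMIs, so a low level may go with maturity. Low depth was excluded, since at the level of the other cells it would give 9.82 Y-linked UMIs.

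A set of 127 genes differed at least 4-fold between the tissues in the same direction in LTi-like and B lineage-like cells at both stages, 14 of them higher and 113 lower in periphery. The cut was made before the all-gene median was taken off. That median was -0.39 and -0.15 in LTi-like and -0.37 and -0.18 in B lineage-like cells at E13.5 and E14.5. Its sign favours the lower direction. Of the 14 higher ones, 64.3% (9 of 14, 35.1 to 87.2) overlapped on their strand a gene model that only the fetal liver list holds, against 1.14% of all measured genes, so counting against such models may be a cause for these 9, Fdx1l and Tonsl among them. The other 5, Srp54c, Fam177a, Btf3l4, Erh and Wdr74, overlapped none and stay unexplained. For the 113 lower ones, among them Fau, Atp5g2 and Klf2, the GC content of the last 500 bases was excluded as an explanation, with a median of 43.2% against 43.4% (quartiles 38.0 to 49.6) for all genes. The reverse overlap, with models that only the periphery list holds, could be tested only in part, since coordinates were found for 317 of its 861 features. Among these, 0 of 110 lower genes (0 to 3.30%) overlapped such a model, against 0.0470% of all measured genes, so it stays open for the other features. A difference of lymphoid cells alone was excluded, since mast cell or basophil-like cells had a median size of 2.80 (2.37 to 3.26) next to 2.77 in LTi-like cells, and no other biological explanation was tested.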
